A study of Mus musculus with 6 samples.

How the data were processed

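RNA of 6 samples was hybridised to 1 Affymetrix array each, from 300 ng of total RNA per sample, and the samples formed 3 groups of 2 that the labels call biological replicates. Nothing in the labels says how many animals or cultures stand behind a replicate, so the p-values measure the spread between arrays. The deposited values are log2, and per the labels the authors made them with Affymetrix Expression Console 1.1 and RMA, which corrects the background, makes the arrays' distributions equal and summarises the probes of a probe set. The table had 35556 probe sets in each of the 6 arrays, with no missing value, and the array medians lay between 6.18 and 6.28. The array annotation gave exactly 1 gene for 21789 probe sets, several genes for 1621 and none for 12146. Where a gene had more than 1 probe set, as 999 genes did, the probe set with the highest mean over the 6 arrays was kept, which left 19938 genes. The genome build behind the annotation is not named, so no coordinates are given. Arrays have no read depth, and 2 arrays per group limit the precision: the median standard error of a log2 difference was 0.132.

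Each comparison was tested with limma 3.58.1 in R 4.3.3 on all 6 arrays together, with 3 residual degrees of freedom, 4.34 prior degrees of freedom, default moderation of the variances, two-sided tests and Benjamini-Hochberg adjustment within a comparison at 0.05. No filter on low values and no pseudocount was used. The comparisons were GM-BMDC minus GM-BMM, GM-BMM minus M-BMM and GM-BMDC minus M-BMM. Genes that set a population apart were those past the threshold in both of its comparisons in the same direction. The distance between populations was the root mean square log2 difference of group means, without a test. Groups of 2 are too small for permutation tests of single values or for a count of other splits of the arrays.

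The lists held 751 entries over 31 lists written from textbook knowledge, of which 700 were measured. They cover the sort gate genes, class II presentation outside the gate, conventional dendritic cells with type 1, type 2 and plasmacytoid markers, dendritic cell maturation and migration, macrophages, monocytes, lung macrophages and PPARγ, and alternative activation. Further lists were scavenger and efferocytosis receptors, complement, C-type lectins, Toll-like receptors, cytokines and chemokines, chemokine receptors, colony-stimulating factor receptors with JAK-STAT feedback, lysosome, cell cycle, glycolysis, cholesterol biosynthesis, type I interferon response, and immediate-early and heat-shock genes. Lists for other cell types were neutrophil, mast cell, eosinophil, B lymphocyte, T and NK lymphocyte, erythroid and fibroblast genes. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons. Of the 93 tests, 52 passed, and 0 of these passed with an estimated correlation. Members were also counted adjusted over the list alone. Several genes belong to more than 1 list.

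The groups, comparisons, tests, lists, the rule for named genes and 21 of the alternatives were set before the data were examined. The rule names, per comparison, the 6 genes with the largest fold in each direction among those past the threshold whose arrays do not overlap, leaving out predicted and clone names. It adds up to 3 members past the threshold with the largest difference from each list described, all genes of the sort gates, and 5 genes of each set that sets a population apart. Xist, the Y-linked genes and the replicate values of single genes fall outside the rule and were chosen after their values were seen. The alternatives set beforehand left out each array in turn, added the replicate number as a block, fitted only the groups compared, changed the variance model, the filter on low values, the normalization, the probe set per gene and the features tested, required a fold, removed the moderation, and tested lists on ranks, with fry or with an estimated correlation. Another 4 alternatives were added after seeing the data: leaving out both GM-CSF arrays numbered 1, leaving out both numbered 2, crossing the M-BMM numbers in the replicate block, and the mean of 3 Y-linked genes as a covariate. Where an alternative leaves 1 array in a group, that array is assumed to vary like those of the other groups.

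The fit was tested on simulated data, with a known fold in 200 of 19938 genes, variances drawn from the fitted prior and the same 6-array layout. At 2-fold it found 77.5%, 76.0% and 76.5% of the changed genes in the 3 comparisons, with 4, 8 and 8 false calls, and at 4-fold 99.5%, 98.5% and 98.0%, with 14, 13 and 17 false calls. At 1.5-fold it found 0 of them by limma after adjustment, a stricter cut than in the data, where more genes were called. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.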

Results

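The series holds 6 arrays of sorted mouse bone marrow cells, 2 from each of 3 populations. Marrow of C57BL/6J mice labelled male and aged 6 to 10 weeks was grown for 7 days. GM-BMDC and GM-BMM came from cultures with 25 ng/ml of GM-CSF, a growth factor that drives myeloid cells, and were separated by their surface markers. GM-BMDC, named dendritic cells in the labels, were sorted as MHCIIhighF4/80low, where MHCII is MHC class II, and GM-BMM as MHCIIlowF4/80high. M-BMM were macrophages from cultures with 20% L cell conditioned medium, a source of M-CSF, sorted on CD11b and on the marker encoded by Adgre1. Each value is an RMA log2 signal. The files mark no background, so a mean under 5.04, the 25th percentile of all values, is called low here, and a fold against a low mean is against a signal not shown to lie above background. With 2 arrays per population, the number of arrays limits the precision. Folds are followed in brackets by the log2 difference and its standard error from limma, with n = 2 arrays in each population.

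The genes of the sorting markers were read first, as a check of the labels. MHC class II genes encode the molecules that present peptides to helper T cells, Adgre1 encodes the macrophage marker used in the 3 gates and Itgam encodes CD11b. H2-Ab1 had a mean of 13.13 ± 0.06 (SD, n = 2) in GM-BMDC, 10.68 ± 0.84 in GM-BMM and 6.08 ± 0.38 in M-BMM. In GM-BMDC against GM-BMM, H2-Aa was 4.63-fold (2.21 ± 0.34), H2-Ab1 5.49-fold (2.46 ± 0.36) and H2-Eb1 6.14-fold (2.62 ± 0.37) higher. Adgre1 was 4.97-fold (-2.31 ± 0.42) lower and Itgam 2.99-fold (-1.58 ± 0.30) lower. H2-Ea, low in every array (4.03 to 4.70), cannot check the sort (log2 difference 0.33 ± 0.18, limma adjusted p = 0.357). GM-BMM stood above M-BMM by 24.4-fold (4.61 ± 0.34) in H2-Aa, 24.2-fold (4.59 ± 0.36) in H2-Ab1 and 7.85-fold (2.97 ± 0.37) in H2-Eb1, although the sort took MHC class II low cells. The log2 differences between GM-BMM and M-BMM were -0.29 ± 0.42 for Adgre1, -0.07 ± 0.30 for Itgam and -0.04 ± 0.18 for H2-Ea (limma adjusted p = 0.797, 0.951 and 0.949). GM-BMDC exceeded M-BMM by 133-fold (7.05 ± 0.36) in H2-Ab1, 113-fold (6.82 ± 0.34) in H2-Aa and 48.2-fold (5.59 ± 0.37) in H2-Eb1, and fell below it by 6.10-fold (-2.61 ± 0.42) in Adgre1 and 3.13-fold (-1.64 ± 0.30) in Itgam. H2-Ea differed by 0.28 ± 0.18 (limma adjusted p = 0.385). As a list, the 6 genes of the gates had 3 higher and 2 lower in GM-BMDC against GM-BMM (camera adjusted p = 0.206), 3 and 0 in GM-BMM against M-BMM (camera adjusted p = 0.0024, or p = 0.336 with an estimated correlation). In GM-BMDC against M-BMM, 3 were higher and 2 lower (camera adjusted p = 0.0469, or p = 0.414 with an estimated correlation), with the same counts in all 3 comparisons when adjusted over the list alone. In GM-BMM against M-BMM the camera call of the list ended on ranks (adjusted p = 0.123). Against M-BMM that of GM-BMDC ended without either GM-BMDC array, M-BMM replicate 2 or both GM-CSF arrays of either number. Genes above the median signal (adjusted p = 0.116) or ranks (0.31) ended it too. As the gates set class II and Adgre1 oppositely, camera on this list cannot check the labels. In GM-BMDC against GM-BMM the list passed in camera without GM-BMM replicate 2. Adgre1 lost its limma call without GM-BMM replicate 2 or with a trended and robust variance (adjusted p = 0.0519). It was also lost with only the groups compared (0.0506), the same fit as without either M-BMM array. Itgam was no longer called by limma without either GM-BMM array or in that fit of only the groups compared (adjusted p = 0.0581). In GM-BMM against M-BMM, H2-Eb1 missed the limma threshold without M-BMM replicate 1 (adjusted p = 0.0689). In GM-BMDC against M-BMM, Adgre1 and Itgam did not pass in limma without either M-BMM array. Single arrays moved differences between GM-BMDC and GM-BMM. Without GM-BMDC replicate 1 or replicate 2, the log2 difference was -1.56 and -3.07 for Adgre1. Leaving out GM-BMM replicate 1 or replicate 2 gave log2 differences of 1.61 and 2.81 for H2-Aa, 1.86 and 3.05 for H2-Ab1 and 1.99 and 3.25 for H2-Eb1. They moved some between GM-BMM and M-BMM. With GM-BMM replicate 1 or replicate 2 left out, the log2 difference was 5.21 and 4.01 for H2-Aa, 5.19 and 3.999 for H2-Ab1 and 3.60 and 2.34 for H2-Eb1. Between GM-BMDC and M-BMM the same held of Adgre1. Without GM-BMDC replicate 1 or replicate 2, the log2 difference was -1.85 and -3.37 for Adgre1.

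**Figure D1:**
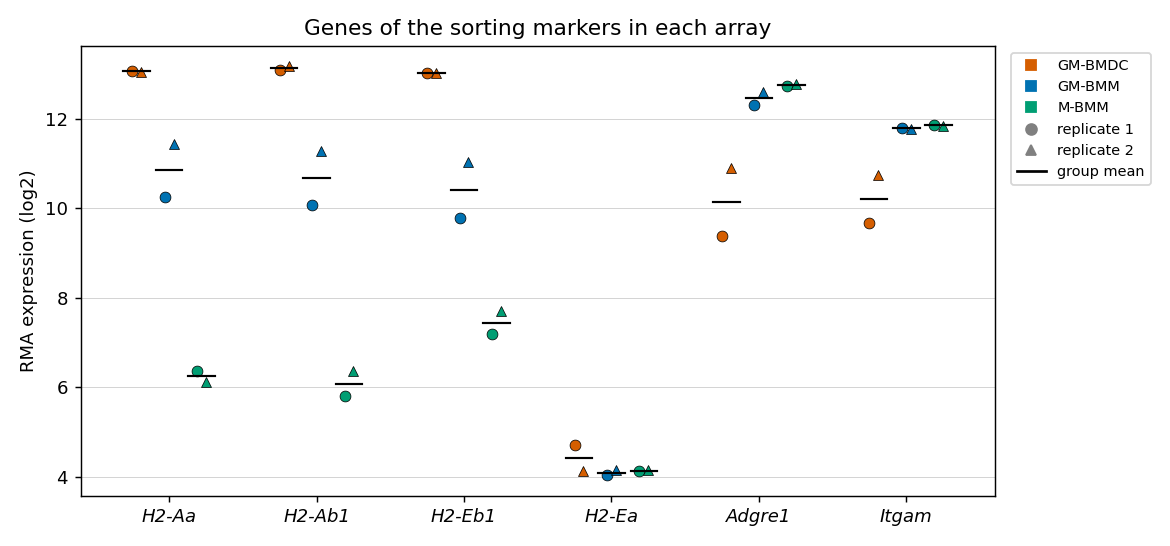
RMA log2 expression of 6 sorting-marker genes in each of the 6 arrays, coloured by population, with circles for replicate 1, triangles for replicate 2 and a bar at each group mean. H2-Aa, H2-Ab1 and H2-Eb1 stepped down from GM-BMDC to GM-BMM to M-BMM, and Adgre1 and Itgam lay lowest in GM-BMDC.

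Xist, the RNA that silences an X chromosome in female cells, and 3 genes of the Y chromosome did not follow the label, which gives every array as male. These genes were chosen after their values were seen. Xist measured 11.66 in GM-BMDC replicate 1, 10.68 in GM-BMDC replicate 2 and 11.58 in GM-BMM replicate 1, against 4.93 in GM-BMM replicate 2, 4.53 in M-BMM replicate 1 and 4.80 in M-BMM replicate 2. The Y-linked translation factor gene Eif2s3y was low in GM-BMDC replicate 1 (3.94) and GM-BMM replicate 1 (3.66) and high in the other 4 arrays (8.80, 9.10, 9.32 and 9.17). Uty and Kdm5d, which encode a pair of histone demethylase family members, followed the same split, with Uty at 3.98 and 3.58 and Kdm5d at 4.90 and 4.68 in those 2 arrays. GM-BMDC replicate 2 carried Xist together with Eif2s3y at 8.80, Uty at 8.17 and Kdm5d at 7.09. Leaving out both GM-CSF arrays numbered 1 left only arrays high in Y-linked RNA, with 1 array in each GM-CSF population, 1 residual degree of freedom and a spread that rests on the 2 M-BMM arrays. Of the arrays left, GM-BMDC replicate 2 also carried Xist, so only GM-BMM and M-BMM were then compared within arrays of a single kind. The counts of that fit, and of a fit with the mean of the 3 Y-linked genes as a covariate, are given beside each count over all genes. Both fits were chosen after the data were seen. Both GM-BMDC arrays and no M-BMM array carried Xist, so the covariate cannot take sex out of their comparison. Xist itself passed in GM-BMDC minus M-BMM (log2 difference 6.50 ± 1.76, limma adjusted p = 0.0445), and the 3 Y-linked genes passed in none of the 3 comparisons.

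**Figure D2:**
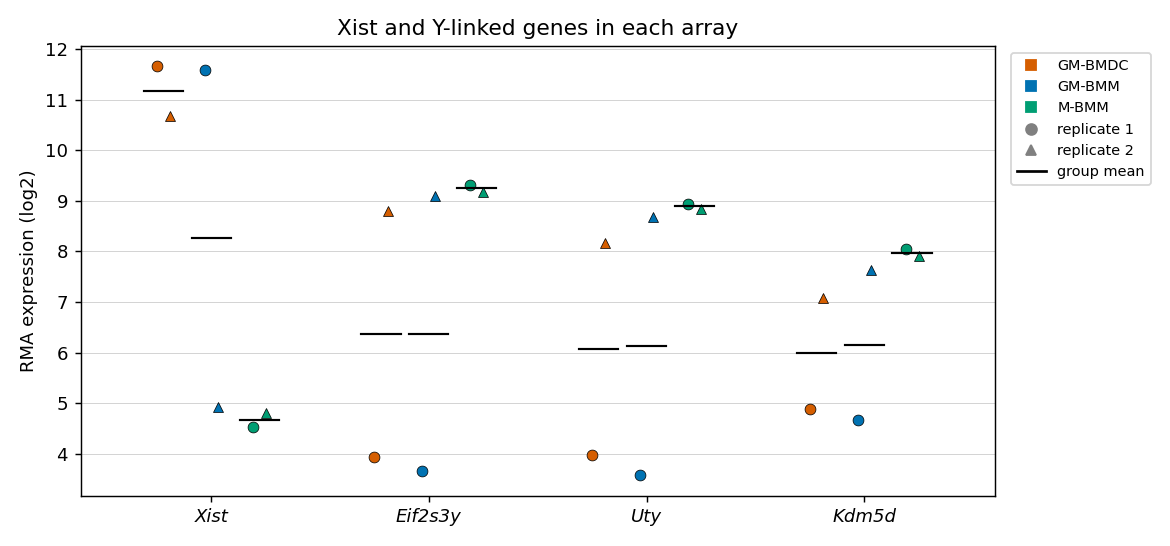
RMA log2 expression of Xist and 3 Y-linked genes in each of the 6 arrays, coloured by population, with circles for replicate 1, triangles for replicate 2 and a bar at each group mean. Xist lay above 10 in GM-BMDC replicate 1, GM-BMDC replicate 2 and GM-BMM replicate 1, and the Y-linked genes lay below 5 in GM-BMDC replicate 1 and GM-BMM replicate 1.

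Over all 19938 genes, the 2 macrophage populations had the closest profiles and GM-BMDC and M-BMM the most distant. The root mean square log2 difference between group means was 0.467 for GM-BMM and M-BMM, 0.522 for GM-BMDC and GM-BMM, and 0.648 for GM-BMDC and M-BMM. Single arrays gave ranges of 0.459 to 0.545, 0.492 to 0.628 and 0.634 to 0.713, so the first 2 ranges overlapped and their order is not settled by the replicates. Replicates of a population lay 0.281 apart in GM-BMDC, 0.310 in GM-BMM and 0.210 in M-BMM, with no test made. Without GM-BMM replicate 2 the order of the 2 smaller distances turned, to 0.529 for GM-BMM and M-BMM and 0.518 for GM-BMDC and GM-BMM.

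The first comparison set the 2 populations of the GM-CSF cultures against each other, which shared the growth factor and differed in the gate. GM-BMDC had more RNA of Ccr7, the receptor that guides dendritic cells to lymph nodes, at 22.4-fold (4.49 ± 0.19) higher, and of Fscn1, an actin-bundling protein, at 31.9-fold (4.99 ± 0.22) higher. GM-BMM had more RNA of Lox, which cross-links collagen, at 40.3-fold (-5.33 ± 0.25) lower in GM-BMDC, and of the gelatinase gene Mmp2 at 21.7-fold (-4.44 ± 0.13) lower. Among the largest differences, Apol7c of the apolipoprotein L family was 45.9-fold (5.52 ± 0.26) higher in GM-BMDC, the immediate-early nuclear receptor gene Nr4a3 45.2-fold (5.50 ± 0.22), the tight-junction gene Cldn1 39.4-fold (5.30 ± 0.33) and the chemokine gene Ccl22 38.4-fold (5.26 ± 0.35). The semaphorin gene Sema6d was 34.0-fold (5.09 ± 0.20) higher. On the other side, Siglece, a receptor for sialic acid, was 23.7-fold (-4.57 ± 0.21) lower, Susd2 22.0-fold (-4.46 ± 0.23), the Schlafen gene Slfn4 21.6-fold (-4.43 ± 0.27) and the androglobin gene Adgb 20.6-fold (-4.37 ± 0.19). Mean levels of Ccr7 were 11.88 ± 0.08 against 7.40 ± 0.02 (SD, n = 2), and those of Lox 5.92 ± 0.19 against 11.25 ± 0.59. Adgb (4.95) was low in GM-BMDC.

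Across all genes, limma found 935 higher and 1144 lower in GM-BMDC, 10.4% of those tested, and 437 and 498 of them differed by at least 2-fold. With the Y-linked covariate the counts were 975 and 1258, and 1943 genes were shared with the fit without it. Without both GM-CSF arrays numbered 1 they were 913 and 1015, with 1399 genes shared. Fitting only the 2 groups compared gave 549 and 658. Many calls thus rest on including M-BMM, whose replicates lay closest. Without GM-BMDC replicate 1 or GM-BMM replicate 2 both counts fell too. Without limma's moderation across genes, 0 genes passed in either direction, with 3686 at an unadjusted p under 0.05.

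Of the 29 conventional dendritic cell genes, 25 were higher in GM-BMDC, 1 lower and 3 did not pass, against 26 and 1 adjusted over the list alone (camera adjusted p = 2.9e-23, or p = 0.178 with an estimated correlation). P2ry10, a receptor for lysophospholipids, was 29.95-fold (4.91 ± 0.26) higher, and Dpp4, a cell-surface peptidase, 17.3-fold (4.12 ± 0.15). Dendritic cell maturation and migration had 26 measured members, of which 20 were higher in GM-BMDC, 0 lower and 6 did not pass, against 21 and 0 adjusted over the list alone (camera adjusted p = 3.99e-15, or p = 0.336 with an estimated correlation). Of the 11 class II presentation genes outside the gate, 7 were higher in GM-BMDC, 0 lower and 4 did not pass, against 7 and 1 adjusted over the list alone (camera adjusted p = 4.04e-06, or p = 0.178 with an estimated correlation). H2-Eb2 was 18.6-fold (4.22 ± 0.19) higher, Ciita, the master regulator of class II transcription, 13.5-fold (3.76 ± 0.20), and H2-Ob 4.69-fold (2.23 ± 0.18). GM-BMDC were sorted as MHCIIhigh, so here and against M-BMM this direction is not independent of the gate. P2ry10 (3.56) was low in GM-BMM.

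Of the 34 macrophage genes, 0 were higher in GM-BMDC, 14 lower and 20 did not pass, against 0 and 21 adjusted over the list alone (camera adjusted p = 3.1e-13, or p = 0.392 with an estimated correlation). The transcription factor gene Maf was 10.1-fold (-3.33 ± 0.39) lower, the tyrosine kinase gene Fer 3.85-fold (-1.95 ± 0.15) and the transporter gene Abcc3 3.77-fold (-1.91 ± 0.27). The lysosome list had 49 measured members, of which 0 were higher in GM-BMDC, 20 lower and 29 did not pass, against 0 and 30 adjusted over the list alone (camera adjusted p = 5.58e-15, or p = 0.336 with an estimated correlation). Ctsk and Ctsl, which encode cathepsin proteases, were 4.23-fold (-2.08 ± 0.22) and 3.02-fold (-1.60 ± 0.19) lower, and Naglu, an enzyme that degrades heparan sulfate, 2.44-fold (-1.29 ± 0.17). Of the 22 Toll-like receptors and adaptors, 1 was higher in GM-BMDC, 11 lower and 10 did not pass, against 1 and 14 adjusted over the list alone (camera adjusted p = 7.14e-06, or p = 0.414 with an estimated correlation). Irak3, a brake on Toll-like receptor signalling, was 5.49-fold (-2.46 ± 0.15) lower, Tlr1 4.95-fold (-2.31 ± 0.43) and Tlr7, a sensor of single-stranded RNA, 4.70-fold (-2.23 ± 0.36). The type I interferon response had 28 measured members, of which 0 were higher in GM-BMDC, 23 lower and 5 did not pass, against 0 and 26 adjusted over the list alone (camera adjusted p = 7.92e-21, or p = 0.336 with an estimated correlation). Ifit3 was 10.5-fold (-3.40 ± 0.44) lower, the transcription factor gene Irf7 8.53-fold (-3.09 ± 0.26) and Oas2, an enzyme that responds to double-stranded RNA, 8.47-fold (-3.08 ± 0.22). Tlr1 was no longer called by limma without GM-BMDC replicate 1 or with a trended and robust variance (adjusted p = 0.057). Nor was it with only the groups compared (0.0546), the same as without either M-BMM array. Leaving out GM-BMDC replicate 1 or replicate 2 gave log2 differences of -2.68 and -3.99 for Maf and -1.59 and -2.88 for Tlr7. With GM-BMM replicate 1 or replicate 2 left out, the log2 difference was -3.08 and -1.53 for Tlr1.

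Of the 42 inflammatory cytokines and chemokines, 5 were higher in GM-BMDC, 17 lower and 20 did not pass, against 6 and 20 adjusted over the list alone (camera adjusted p = 8.96e-06, or p = 0.284 with an estimated correlation). The monocyte attractant gene Ccl7 was 10.3-fold (-3.37 ± 0.19) lower in GM-BMDC, whereas Ccl22 and Ccl17, which attract cells bearing CCR4, were higher, Ccl17 by 21.4-fold (4.42 ± 1.05). The monocyte list had 17 measured members, of which 1 was higher in GM-BMDC, 8 lower and 8 did not pass, against 1 and 9 adjusted over the list alone (camera adjusted p = 0.000485, or p = 0.284 with an estimated correlation). The haptoglobin gene Hp was 19.0-fold (-4.25 ± 0.40) lower, the chitinase-like gene Chil3 10.1-fold (-3.33 ± 0.34) and Plac8 6.51-fold (-2.70 ± 0.18). Of the 23 neutrophil and granule genes, 0 were higher in GM-BMDC, 7 lower and 16 did not pass, against 1 and 12 adjusted over the list alone (camera adjusted p = 2.15e-05, or p = 0.284 with an estimated correlation). Mmp9, another gelatinase, was 17.4-fold (-4.12 ± 0.13) lower, the G-CSF receptor gene Csf3r 8.01-fold (-3.002 ± 0.38) and Lcn2, which binds bacterial siderophores, 5.40-fold (-2.43 ± 0.20). Ccl17 missed the limma threshold without either GM-BMDC array or with a trended and robust variance (adjusted p = 0.184). It also missed it with only the groups compared (0.103), the same as without either M-BMM array. Without GM-BMDC replicate 1 or replicate 2, the log2 difference was -3.65 and -4.85 for Hp and -2.32 and -3.69 for Csf3r. Leaving out GM-BMM replicate 1 or replicate 2 gave log2 differences of 6.42 and 2.42 for Ccl17. Chil3 had log2 differences of -2.65 and -4.004 without both GM-CSF arrays numbered 1 or both numbered 2.

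Of the 20 genes of cholesterol biosynthesis, 9 were higher in GM-BMDC, 0 lower and 11 did not pass, against 14 and 0 adjusted over the list alone (camera adjusted p = 2.8e-08, or p = 0.392 with an estimated correlation). Idi1, which makes isoprenoid precursors, was 5.04-fold (2.33 ± 0.28) higher, and the sterol demethylase gene Cyp51 2.41-fold (1.27 ± 0.24). Of the 21 genes of glycolysis, 1 was higher in GM-BMDC, 11 lower and 9 did not pass, against 1 and 14 adjusted over the list alone (camera adjusted p = 2e-07, or p = 0.336 with an estimated correlation). Pfkl, a phosphofructokinase gene, was 2.96-fold (-1.57 ± 0.20) lower, and the hexokinase genes Hk2 and Hk3 2.42-fold (-1.28 ± 0.17) and 2.19-fold (-1.13 ± 0.15). Of the 25 immediate-early and heat-shock genes, a list written as a sign of handling, 2 were higher in GM-BMDC, 3 lower and 20 did not pass, against 4 and 3 adjusted over the list alone (camera adjusted p = 0.965, not past the threshold). Nr4a3, given above, led it, with its relative Nr4a2 at 4.19-fold (2.07 ± 0.16) higher, and the list had a mean of 0.15 and a median of -0.05. Cyp51 did not pass in limma without GM-BMDC replicate 1 (adjusted p = 0.0599), GM-BMDC replicate 2 (0.0683), GM-BMM replicate 2 (0.0752) or both GM-CSF arrays numbered 2 (0.0838).

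Of the 14 type 1 conventional dendritic cell markers, 4 were higher in GM-BMDC, 1 lower and 9 did not pass, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.0146, or p = 0.336 with an estimated correlation), with the sensor gene Tlr3 4.08-fold (-2.03 ± 0.32) lower and the transcription factor gene Batf3 2.64-fold (1.40 ± 0.18) higher. Of the 13 type 2 conventional dendritic cell markers, 6 were higher in GM-BMDC, 1 lower and 6 did not pass, against 8 and 1 adjusted over the list alone (camera adjusted p = 0.000331, or p = 0.336 with an estimated correlation), with the lectin gene Cd209a 21.6-fold (4.43 ± 0.74) higher. Of the 25 alternative activation genes, 8 were higher in GM-BMDC, 4 lower and 13 did not pass, against 12 and 5 adjusted over the list alone (camera adjusted p = 0.00508, or p = 0.597 with an estimated correlation), led by Ccl22 and Ccl17. Of the 28 scavenger and efferocytosis receptors, 2 were higher in GM-BMDC, 8 lower and 18 did not pass, against 3 and 11 adjusted over the list alone (camera adjusted p = 0.0264, or p = 0.424 with an estimated correlation), with Marco 9.31-fold (-3.22 ± 0.34) and Stab1 3.83-fold (-1.94 ± 0.30) lower. Of the 27 lung macrophage and PPARγ genes, 5 were higher in GM-BMDC, 7 lower and 15 did not pass, against 5 and 7 adjusted over the list alone (camera adjusted p = 0.187, not past the threshold), a list that passed in camera without GM-BMM replicate 2 (adjusted p = 0.00193). The type 1 list lost its camera call without GM-BMDC replicate 2 (adjusted p = 0.0684), GM-BMM replicate 2 (0.0594), both GM-CSF arrays numbered 2 (0.174) or with only genes above the median signal (0.0789). That of alternative activation ended without both GM-CSF arrays numbered 2 (adjusted p = 0.0542). Scavenger receptors lost theirs without GM-BMM replicate 1 (adjusted p = 0.269), both GM-CSF arrays numbered 1 (0.525) or on ranks (0.155). Cd209a lost its limma call without GM-BMM replicate 2 (adjusted p = 0.0523) or with a trended and robust variance (0.0749). With GM-BMDC replicate 1 or replicate 2 left out, the log2 difference was 5.76 and 3.11 for Cd209a. Without GM-BMM replicate 1 or replicate 2, the log2 difference was -3.82 and -2.61 for Marco.

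The second comparison set the MHCIIlowF4/80high cells of the GM-CSF cultures against the macrophages of the M-CSF cultures, so the growth factor and the gate both differed. GM-BMM had more RNA of Cxcl3, a neutrophil attractant, at 29.7-fold (4.89 ± 0.33) higher, and of the cytokine genes Il1a at 17.8-fold (4.15 ± 0.35) and Il6 at 13.9-fold (3.79 ± 0.30) higher. Itgax, which encodes CD11c and is high in lung macrophages, was 23.0-fold (4.53 ± 0.22) higher. Cd5l, a protein secreted by tissue macrophages, was 40.4-fold (-5.33 ± 0.14) lower in GM-BMM. The largest differences upward were those of the class I-like gene H2-M2 at 68.2-fold (6.09 ± 0.28), Plxdc2 at 52.1-fold (5.70 ± 0.20), the cationic amino acid transporter gene Slc7a2 at 46.4-fold (5.54 ± 0.16) and the kallikrein gene Klk1b11 at 39.2-fold (5.29 ± 0.66). Inhba, a subunit of activin A, followed at 33.5-fold (5.07 ± 0.43) and the acid phosphatase gene Acpp at 33.3-fold (5.06 ± 0.16). Downward, the dicarboxylate transporter gene Slc13a3 was 25.1-fold (-4.65 ± 0.86) lower, the complement inhibitor gene Cd55 19.6-fold (-4.29 ± 0.21), Raver2 17.0-fold (-4.09 ± 0.64), the phosphatase gene Ptprm 14.4-fold (-3.85 ± 0.22) and the sulfotransferase gene Ust 13.6-fold (-3.77 ± 0.20). Mean levels of Il6 were 8.78 ± 0.50 against 4.99 ± 0.23 (SD, n = 2), and those of Cd5l 6.06 ± 0.18 against 11.40 ± 0.03. Leaving out GM-BMM replicate 1 or replicate 2 gave log2 differences of 4.05 and 6.53 for Klk1b11, -3.02 and -6.27 for Slc13a3 and -2.89 and -5.29 for Raver2. Klk1b11 was no longer called by limma without M-BMM replicate 1 (adjusted p = 0.0631) or M-BMM replicate 2 (0.0739). Slc13a3 missed the limma threshold without M-BMM replicate 1 (adjusted p = 0.16), M-BMM replicate 2 (0.184) or with a trended and robust variance (0.137). Raver2 did not pass in limma without M-BMM replicate 1 (adjusted p = 0.119), M-BMM replicate 2 (0.121) or with a trended and robust variance (0.0757). Il6 (4.99) was low in M-BMM. Klk1b11, Inhba, Slc13a3 and Raver2 had log2 differences of 4.53, 4.41, -3.58 and -3.21 with the Y-linked covariate.

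In total, 722 genes were higher and 513 lower in GM-BMM by limma, 6.19% of those tested, and 426 and 177 of them differed by at least 2-fold. With the Y-linked covariate the counts were 597 and 302, and 788 genes were shared with the fit without it. Among arrays high in Y-linked RNA, left when both GM-CSF arrays numbered 1 were taken out, they were 974 and 600, with 1037 genes shared. Without M-BMM replicate 1 the counts were 249 and 92, and without M-BMM replicate 2 they were 217 and 102. The lower count was 279 without GM-BMM replicate 1. Leaving out both GM-CSF arrays numbered 2, a choice made after the data were seen, gave 1168 and 880. Without limma's moderation across genes, 6 and 2 genes passed.

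Of the 42 inflammatory cytokines and chemokines, 19 were higher in GM-BMM, 0 lower and 23 did not pass, against 22 and 1 adjusted over the list alone (camera adjusted p = 5.58e-15, or p = 0.178 with an estimated correlation). The list of lung macrophage and PPARγ genes had 27 measured members, of which 14 were higher in GM-BMM, 0 lower and 13 did not pass, against 16 and 1 adjusted over the list alone (camera adjusted p = 1.76e-14, or p = 0.178 with an estimated correlation). Slc7a2 and Itgax, given above, led it, with Atp6v0d2, a subunit of the vacuolar proton pump, at 21.1-fold (4.40 ± 0.38) higher. Of the 25 alternative activation genes, 11 were higher in GM-BMM, 1 lower and 13 did not pass, against 13 and 2 adjusted over the list alone (camera adjusted p = 3.8e-09, or p = 0.383 with an estimated correlation). Mmp12, the macrophage elastase gene, was 30.3-fold (4.92 ± 0.16) higher, the transcription factor gene Egr2 11.8-fold (3.56 ± 0.25) and Chil3 11.8-fold (3.56 ± 0.34). Of the 11 class II presentation genes outside the gate, 5 were higher in GM-BMM, 0 lower and 6 did not pass, against 9 and 0 adjusted over the list alone (camera adjusted p = 3.8e-09, or p = 0.178 with an estimated correlation). The invariant chain gene Cd74 was 13.9-fold (3.79 ± 0.16) higher, H2-DMa, which exchanges peptides, 3.55-fold (1.83 ± 0.22) and H2-Oa 2.78-fold (1.48 ± 0.14). With GM-BMM replicate 1 or replicate 2 left out, the log2 difference was 3.74 and 5.06 for Atp6v0d2. H2-DMa lost its limma call without M-BMM replicate 1 (adjusted p = 0.0636) or M-BMM replicate 2 (0.0611).

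Of the 26 genes of colony-stimulating factor receptors and JAK-STAT feedback, 7 were higher in GM-BMM, 1 lower and 18 did not pass, against 11 and 2 adjusted over the list alone (camera adjusted p = 1.35e-05, or p = 0.178 with an estimated correlation). Csf2rb, the shared receptor chain for GM-CSF, IL-3 and IL-5, was 3.99-fold (1.996 ± 0.19) higher and its relative Csf2rb2 5.46-fold (2.45 ± 0.18), with the feedback inhibitor gene Socs2 at 8.74-fold (3.13 ± 0.66). Of the 21 genes of glycolysis, 7 were higher in GM-BMM, 0 lower and 14 did not pass, against 11 and 0 adjusted over the list alone (camera adjusted p = 8.89e-09, or p = 0.336 with an estimated correlation). The aldolase gene Aldoc was 10.4-fold (3.37 ± 0.17) higher, the lactate exporter gene Slc16a3 2.66-fold (1.41 ± 0.12) and the glucose transporter gene Slc2a1 2.26-fold (1.18 ± 0.11). Of the 25 immediate-early and heat-shock genes, 3 were higher in GM-BMM, 0 lower and 22 did not pass, against 6 and 0 adjusted over the list alone (camera adjusted p = 0.000113, or p = 0.336 with an estimated correlation). Egr2 belongs to it too, and Ier3 was 2.06-fold (1.04 ± 0.23) and the chaperone gene Hsph1 1.53-fold (0.61 ± 0.14) higher. Without GM-BMM replicate 1 or replicate 2, the log2 difference was 1.92 and 4.34 for Socs2. Socs2 was no longer called by limma without either M-BMM array, with a trended and robust variance (adjusted p = 0.143) or with the mean of all probe sets (0.0753). Nor was it with only the groups compared (0.0513), the same as without either GM-BMDC array. The limma calls of Ier3 and Hsph1 ended without GM-BMM replicate 1, M-BMM replicate 1 or M-BMM replicate 2, with the replicate block (adjusted p = 0.0561 and 0.0545), after quantile normalization again or with the Y-linked covariate. That of Hsph1 also ended without GM-BMM replicate 2 or both GM-CSF arrays numbered 2. Socs2 (4.99) was low in M-BMM. Socs2 had log2 differences of 2.10 with the mean of all probe sets and 2.21 with the Y-linked covariate.

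Of the 28 scavenger and efferocytosis receptors, 6 were higher in GM-BMM, 2 lower and 20 did not pass, against 6 and 3 adjusted over the list alone (camera adjusted p = 0.0306, or p = 0.435 with an estimated correlation). Beside Cd5l, the receptor gene for oxidised LDL Olr1 was 15.9-fold (3.99 ± 0.31) higher and Axl, a receptor for apoptotic cells, 9.72-fold (3.28 ± 0.13). The camera call of this list ended without GM-BMM replicate 1 (adjusted p = 0.334), M-BMM replicate 2 (0.0968), both GM-CSF arrays numbered 1 (0.31) or on ranks (0.0973). Of the 29 C-type lectin receptors, 6 were higher in GM-BMM, 1 lower and 22 did not pass, against 7 and 2 adjusted over the list alone (camera adjusted p = 0.113, not past the threshold). Clec7a, which binds fungal glucans, was 10.9-fold (3.44 ± 0.21) higher, Clec9a, a receptor for dead cells, 5.43-fold (2.44 ± 0.23) and the endocytic receptor gene Ly75 5.22-fold (2.38 ± 0.27). This list passed in camera without GM-BMM replicate 2 (adjusted p = 0.0144). Of the 23 chemokine receptors, 4 were higher in GM-BMM, 1 lower and 18 did not pass, against 6 and 2 adjusted over the list alone (camera adjusted p = 0.144, not past the threshold). Ccr2, which draws monocytes out of marrow, was 7.99-fold (2.997 ± 0.39) higher and Cxcr4 2.84-fold (1.503 ± 0.14). Ly75 missed the limma threshold without M-BMM replicate 2 (adjusted p = 0.0564). Ccr2 did not pass in limma without M-BMM replicate 2 (adjusted p = 0.0504). Clec9a (4.96) was low in M-BMM.

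The type I interferon list, which was lower in GM-BMDC against GM-BMM, had 28 measured members, of which 1 was higher in GM-BMM, 0 lower and 27 did not pass, against 3 and 0 adjusted over the list alone (camera adjusted p = 0.00778, or p = 0.701 with an estimated correlation). Its member Oas3 was 2.07-fold (1.05 ± 0.22) higher. The mean log2 difference of the list was 0.23, and without GM-BMM replicate 2 it turned to -0.12 (camera adjusted p = 0.365). It was the same without both GM-CSF arrays numbered 2 (camera adjusted p = 0.227), and without M-BMM replicate 2 the camera call ended (adjusted p = 0.118). Oas3 lost its limma call without either M-BMM array. It also lost it with only the groups compared (adjusted p = 0.0503), the same as without either GM-BMDC array.

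Of the 17 monocyte markers, 5 were higher in GM-BMM, 0 lower and 12 did not pass, against 7 and 2 adjusted over the list alone (camera adjusted p = 2.38e-06, or p = 0.185 with an estimated correlation), with the fibronectin gene Fn1 27.1-fold (4.76 ± 0.20) and Hp 10.1-fold (3.34 ± 0.40) higher. Of the 29 conventional dendritic cell genes, 5 were higher in GM-BMM, 1 lower and 23 did not pass, against 8 and 1 adjusted over the list alone (camera adjusted p = 0.000332, or p = 0.392 with an estimated correlation), with the protease gene Napsa 6.82-fold (2.77 ± 0.15) higher. Of the 26 genes of dendritic cell maturation and migration, 9 were higher in GM-BMM, 2 lower and 15 did not pass, against 9 and 3 adjusted over the list alone (camera adjusted p = 0.0102, or p = 0.645 with an estimated correlation), with the chemokine gene Ccl5 9.57-fold (3.26 ± 0.19) higher. Of the 14 type 1 conventional dendritic cell markers, 5 were higher in GM-BMM, 0 lower and 9 did not pass, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.00584, or p = 0.336 with an estimated correlation), with Cd24a 11.7-fold (3.55 ± 0.43) higher. Of the 20 genes of cholesterol biosynthesis, 1 was higher in GM-BMM, 0 lower and 19 did not pass, against 5 and 0 adjusted over the list alone (camera adjusted p = 2.24e-05, or p = 0.452 with an estimated correlation), with Mvd 1.97-fold (0.98 ± 0.12) higher. The maturation list lost its camera call with only genes above the median signal (adjusted p = 0.0591), on ranks (0.108) or with the Y-linked covariate (0.2). The type 1 list lost it on ranks (adjusted p = 0.107). Hp was no longer called by limma without M-BMM replicate 1 (adjusted p = 0.0506) or M-BMM replicate 2 (0.0692). Cd24a missed the limma threshold without M-BMM replicate 1 (adjusted p = 0.0506) or M-BMM replicate 2 (0.0676). Mvd did not pass in limma without M-BMM replicate 1 (adjusted p = 0.0643). Leaving out GM-BMM replicate 1 or replicate 2 gave log2 differences of 2.79 and 4.32 for Cd24a. Hp had a log2 difference of 3.95 with the Y-linked covariate.

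The third comparison set GM-BMDC against M-BMM, the 2 populations with the most distant profiles. The chemokine genes Ccl17 and Ccl22 were 147-fold (7.20 ± 1.05) and 132-fold (7.05 ± 0.35) higher in GM-BMDC, and Ccr7 50.2-fold (5.65 ± 0.19). Socs2, a feedback inhibitor of cytokine receptors, was 108-fold (6.76 ± 0.66) higher and Klk1b11 155-fold (7.28 ± 0.66), while H2-Ab1 and H2-Aa, given above, were the others among the 6 largest. Folds of this size lean on the lower signal, which in M-BMM was low for Socs2 (4.99) and not far above that for Klk1b11 (5.80), so their order among the largest is not settled. M-BMM had more of Slc13a3, at 176-fold (-7.46 ± 0.86) lower in GM-BMDC, of Cd5l, at 69.7-fold (-6.12 ± 0.14), and of the ceruloplasmin gene Cp, a copper-binding oxidase, at 43.3-fold (-5.44 ± 0.17). Raver2 was 62.8-fold (-5.97 ± 0.64) lower, Cd55 39.7-fold (-5.31 ± 0.21) and Siglece 33.7-fold (-5.07 ± 0.21). Mean levels of Ccl22 were 12.24 ± 0.17 against 5.20 ± 0.36 (SD, n = 2), and those of Slc13a3 5.91 ± 0.01 against 13.37 ± 0.12. Cd55 (4.34) was low in GM-BMDC. Socs2 had a log2 difference of 5.39 with the mean of all probe sets. Ccl17, Socs2, Klk1b11, Slc13a3 and Raver2 had log2 differences of 5.78, 5.81, 6.49, -6.37 and -5.07 with the Y-linked covariate.

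By limma, 1548 genes were higher and 1775 lower in GM-BMDC, 16.7% of those tested, with 771 and 614 at 2-fold or more. With the Y-linked covariate the counts were 1085 and 1029, and 2043 genes were shared with the fit without it. With both GM-CSF arrays numbered 1 left out they were 1591 and 1522, with 2635 genes shared. The higher count was 731 without M-BMM replicate 1 and 733 without M-BMM replicate 2. The lower count was 941 without GM-BMDC replicate 1, 557 without M-BMM replicate 1 and 729 without M-BMM replicate 2. Without limma's moderation across genes, 8 and 9 genes passed.

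Of the 11 class II presentation genes outside the gate, 7 were higher in GM-BMDC, 0 lower and 4 did not pass, against 8 and 0 adjusted over the list alone (camera adjusted p = 9.09e-11, or p = 0.178 with an estimated correlation). Cd74 was 42.0-fold (5.39 ± 0.16) higher, H2-Eb2 25.9-fold (4.70 ± 0.19) and Ciita 20.1-fold (4.33 ± 0.20). Of the 29 conventional dendritic cell genes, 24 were higher in GM-BMDC, 1 lower and 4 did not pass, against 25 and 2 adjusted over the list alone (camera adjusted p = 2.35e-21, or p = 0.178 with an estimated correlation). P2ry10 was 31.1-fold (4.96 ± 0.26) higher and Dpp4 16.4-fold (4.04 ± 0.15), beside Ccr7. In this comparison, dendritic cell maturation and migration had 26 measured members, of which 20 were higher in GM-BMDC, 0 lower and 6 did not pass, against 21 and 0 adjusted over the list alone (camera adjusted p = 7.52e-16, or p = 0.336 with an estimated correlation). Of the 14 type 1 conventional dendritic cell markers, 9 were higher in GM-BMDC, 2 lower and 3 did not pass, against 9 and 2 adjusted over the list alone (camera adjusted p = 6.56e-05, or p = 0.211 with an estimated correlation). Cd24a, a surface glycoprotein gene, was 37.7-fold (5.24 ± 0.43) higher, the acid amidase gene Naaa 9.80-fold (3.29 ± 0.24) and Ly75 7.00-fold (2.81 ± 0.27). Of the 13 type 2 conventional dendritic cell markers, 7 were higher in GM-BMDC, 3 lower and 3 did not pass, against 10 and 3 adjusted over the list alone (camera adjusted p = 0.000978, or p = 0.37 with an estimated correlation). The lectin genes Mgl2 and Cd209a were 45.5-fold (5.51 ± 0.96) and 32.9-fold (5.04 ± 0.74) higher, and Irf4, a transcription factor gene, 27.3-fold (4.77 ± 0.34). With GM-BMDC replicate 1 or replicate 2 left out, the log2 difference was 6.36 and 3.72 for Cd209a. Mgl2 lost its limma call without M-BMM replicate 1 (adjusted p = 0.0837), M-BMM replicate 2 (0.0651) or with a trended and robust variance (0.0709). Cd209a was no longer called by limma without M-BMM replicate 1 (adjusted p = 0.0525). P2ry10 (3.50) was low in M-BMM. Mgl2 had a log2 difference of 4.40 with the Y-linked covariate.

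Of the 34 macrophage genes, 2 were higher in GM-BMDC, 17 lower and 15 did not pass, against 2 and 21 adjusted over the list alone (camera adjusted p = 1.2e-06, or p = 0.51 with an estimated correlation). Maf was 19.2-fold (-4.27 ± 0.39) lower, Fer 9.62-fold (-3.27 ± 0.15) and the selenium transport gene Selenop 4.03-fold (-2.01 ± 0.38). Of the 22 Toll-like receptors and adaptors, 2 were higher in GM-BMDC, 8 lower and 12 did not pass, against 2 and 11 adjusted over the list alone (camera adjusted p = 0.00294, or p = 0.554 with an estimated correlation). Tlr1 was 14.6-fold (-3.87 ± 0.43) lower, Irak3 4.49-fold (-2.17 ± 0.15) and Tlr7 4.23-fold (-2.08 ± 0.36). Against M-BMM, the type I interferon response had 28 measured members, of which 0 were higher in GM-BMDC, 21 lower and 7 did not pass, against 1 and 22 adjusted over the list alone (camera adjusted p = 1.39e-13, or p = 0.392 with an estimated correlation). Ifit3 was 11.4-fold (-3.51 ± 0.44) lower, Ifit2 10.5-fold (-3.39 ± 0.40) and Oas2 10.4-fold (-3.38 ± 0.22). Without GM-BMDC replicate 1 or replicate 2, the log2 difference was -3.61 and -4.92 for Maf, -1.32 and -2.70 for Selenop and -1.44 and -2.72 for Tlr7. Selenop missed the limma threshold without M-BMM replicate 1 (adjusted p = 0.104), M-BMM replicate 2 (0.0838) or with the Y-linked covariate (0.0504). Tlr7 did not pass in limma without M-BMM replicate 1 (adjusted p = 0.0819) or M-BMM replicate 2 (0.0598). Tlr1 and Ifit3 had log2 differences of -3.24 and -2.80 with the Y-linked covariate.

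Among the 20 genes of cholesterol biosynthesis, 15 were higher in GM-BMDC, 0 lower and 5 did not pass, against 18 and 0 adjusted over the list alone (camera adjusted p = 8.82e-12, or p = 0.336 with an estimated correlation). Idi1 was 7.36-fold (2.88 ± 0.28) higher, Cyp51 3.89-fold (1.96 ± 0.24) and the epoxidase gene Sqle 3.19-fold (1.67 ± 0.19). Of the 48 cell cycle genes, 6 were higher in GM-BMDC, 1 lower and 41 did not pass, against 6 and 1 adjusted over the list alone (camera adjusted p = 0.00418, or p = 0.658 with an estimated correlation). The centromere gene Cenpa was 2.81-fold (1.49 ± 0.23) higher and the transcription factor gene E2f1 2.02-fold (-1.01 ± 0.14) lower. The camera call of the cell cycle list ended without GM-BMDC replicate 2 (adjusted p = 0.113), M-BMM replicate 2 (0.136) or both GM-CSF arrays numbered 2 (0.0542). Among the 25 immediate-early and heat-shock genes, 6 were higher in GM-BMDC, 1 lower and 18 did not pass, against 7 and 2 adjusted over the list alone (camera adjusted p = 0.00839, or p = 0.414 with an estimated correlation). Nr4a3 was 78.1-fold (6.29 ± 0.22), Egr2 22.7-fold (4.50 ± 0.25) and Nr4a2 4.50-fold (2.17 ± 0.16) higher. Cenpa lost its limma call without M-BMM replicate 2 (adjusted p = 0.0539). Nr4a3 (4.92) was low in M-BMM.

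Of the 27 lung macrophage and PPARγ genes, 15 were higher in GM-BMDC, 2 lower and 10 did not pass, against 17 and 2 adjusted over the list alone (camera adjusted p = 5.3e-08, or p = 0.211 with an estimated correlation), with Itgax 62.9-fold (5.97 ± 0.22) and the desaturase gene Scd1 28.3-fold (4.82 ± 0.21) higher. Of the 25 alternative activation genes, 14 were higher in GM-BMDC, 1 lower and 10 did not pass, against 17 and 1 adjusted over the list alone (camera adjusted p = 5.51e-09, or p = 0.383 with an estimated correlation), led by Ccl17, Ccl22 and Socs2. Of the 26 genes of colony-stimulating factor receptors and JAK-STAT feedback, 11 were higher in GM-BMDC, 4 lower and 11 did not pass, against 12 and 4 adjusted over the list alone (camera adjusted p = 0.00603, or p = 0.284 with an estimated correlation), with Csf3r 14.5-fold (-3.86 ± 0.38) lower. Of the 42 inflammatory cytokines and chemokines, 15 were higher in GM-BMDC, 9 lower and 18 did not pass, against 18 and 10 adjusted over the list alone (camera adjusted p = 0.0303, or p = 0.414 with an estimated correlation), with Il10 20.8-fold (-4.38 ± 0.65) lower. Of the 16 complement components and receptors, 1 was higher in GM-BMDC, 3 lower and 12 did not pass, against 1 and 6 adjusted over the list alone (camera adjusted p = 0.0445, or p = 0.405 with an estimated correlation), with the receptor gene C3ar1 2.39-fold (-1.25 ± 0.17) lower. Of the 49 genes of the lysosome, 1 was higher in GM-BMDC, 23 lower and 25 did not pass, against 3 and 29 adjusted over the list alone (camera adjusted p = 1.84e-06, or p = 0.452 with an estimated correlation), with Gaa 2.78-fold (-1.47 ± 0.11) and Ctsl 2.73-fold (-1.45 ± 0.19) lower. Of the 17 monocyte markers, 5 were higher in GM-BMDC, 6 lower and 6 did not pass, against 5 and 7 adjusted over the list alone (camera adjusted p = 0.58, not past the threshold), with a mean of 0.08 and a median of -0.64, and the test pointed down. The receptor and feedback list lost its camera call on ranks (adjusted p = 0.0973). Cytokines and chemokines lost theirs without GM-BMDC replicate 1 (adjusted p = 0.0669), M-BMM replicate 2 (0.0943) or on ranks (0.0958). The complement list lost it without GM-BMDC replicate 1 (adjusted p = 0.0863), M-BMM replicate 1 (0.114), with only genes above the median signal (0.136) or with the Y-linked covariate (0.051). Leaving out GM-BMDC replicate 1 or replicate 2 gave log2 differences of -3.18 and -4.54 for Csf3r. Il10 (4.25) was low in GM-BMDC. Il10 had a log2 difference of -3.65 with the Y-linked covariate.

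**Figure D3:**
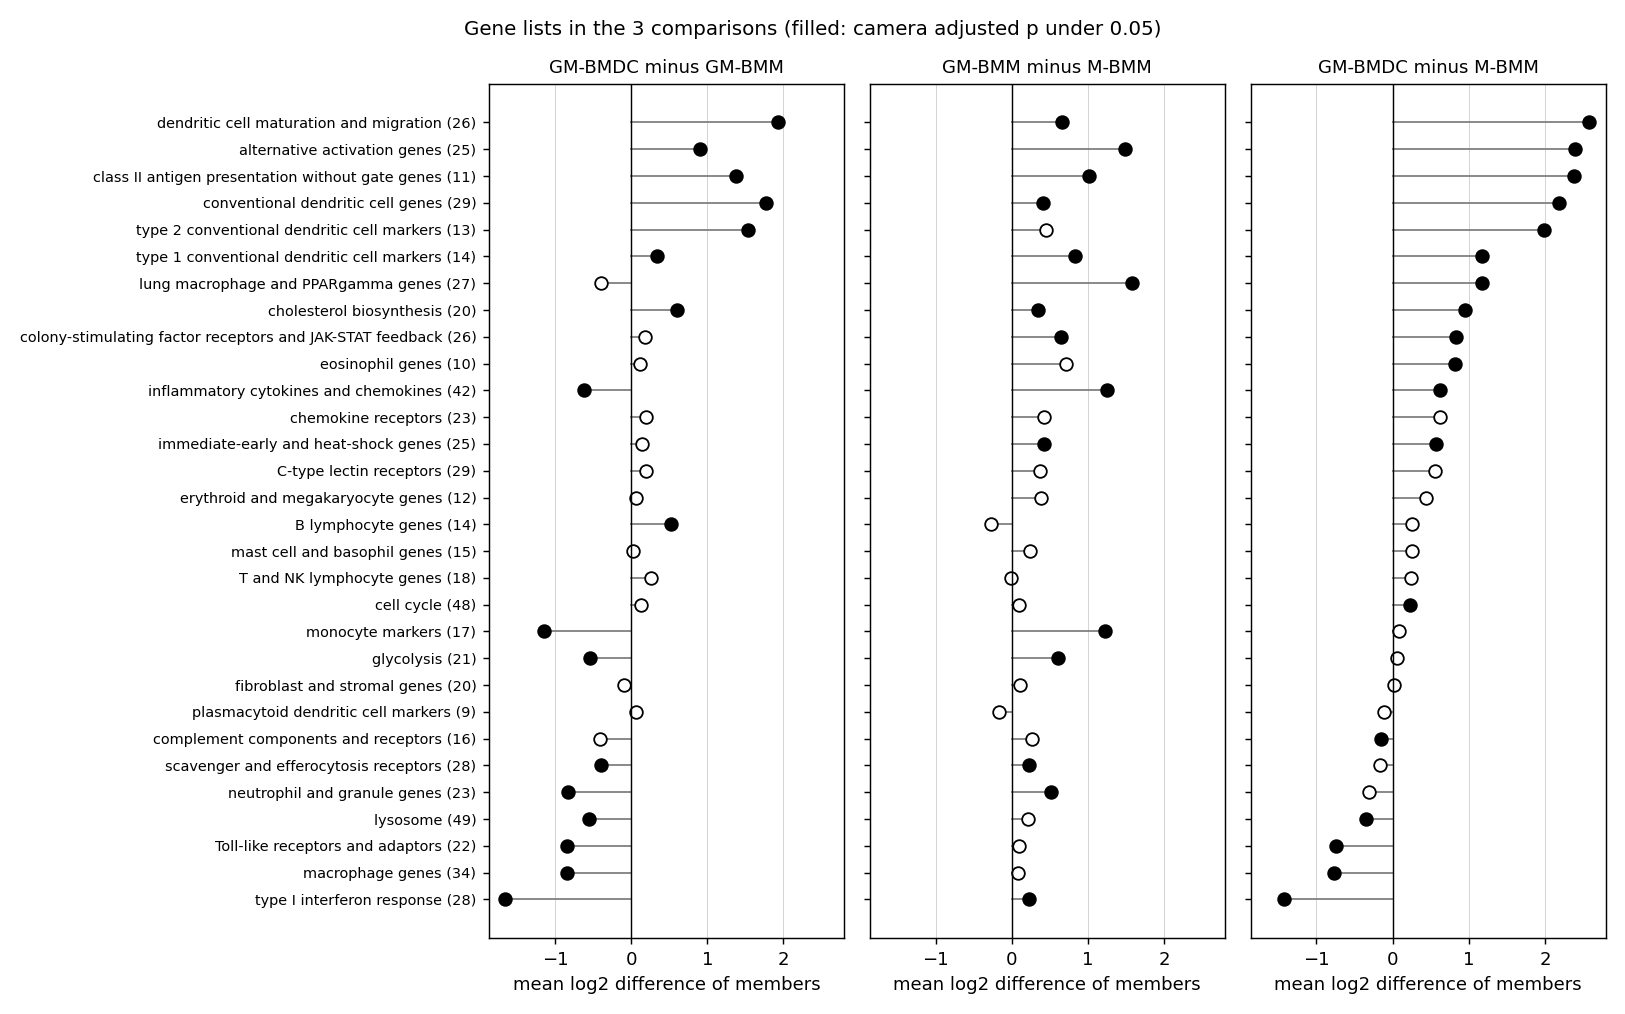
Mean log2 difference of the measured members of each gene list in the 3 comparisons, without the list of sort gate genes, with the number of measured members in brackets. Filled points passed camera at adjusted p under 0.05, a call that no list kept with an estimated correlation, and in GM-BMDC against either other population the lists of conventional dendritic cells and of maturation lay to the right and the type I interferon list to the left, with plasmacytoid markers at 0.07 and -0.11.

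Genes that set a population apart from both others were counted where both of its comparisons passed in the same direction. GM-BMDC had 720 genes higher and 671 lower than both macrophage populations, GM-BMM 276 and 75, and M-BMM 377 and 400. Independent lists of these sizes would share 72.6, 101.8, 41.4, 24.1, 45.7 and 56.1 genes in the same order, and 100 simulated sets without any difference, where almost no gene is called, shared at most 1. The first value leaves out the arrays that the comparisons share and the second the differences, so neither gives the overlap that chance adds here. Without M-BMM replicate 1 the counts were 377, 228, 107, 11, 77 and 142, and without M-BMM replicate 2 they were 385, 264, 90, 11, 91 and 135. GM-BMDC counts were 468 higher and 285 lower without GM-BMDC replicate 1, and 437 lower without GM-BMM replicate 2. Genes higher in M-BMM numbered 215 without GM-BMM replicate 1. In the order given first, the 6 counts were 626, 538, 285, 74, 209 and 300 with the Y-linked covariate, and 731, 606, 386, 127, 380 and 494 without both GM-CSF arrays numbered 1.

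Apol7c, Nr4a3, Cldn1, Ccl22 and Sema6d led the genes high in GM-BMDC, with Sema6d 34.0-fold and 34.4-fold above GM-BMM and M-BMM. Those low in GM-BMDC were led by Siglece, Lox, Cp, Fcgr4 and Klra2, with Siglece 23.7-fold and 33.7-fold below GM-BMM and M-BMM. High in GM-BMM were Susd2, the Ly6 family genes Ly6a2 and Ly6i, the arginase gene Arg1 and the prostaglandin E synthase gene Ptges, with Arg1 12.1-fold and 11.8-fold above GM-BMDC and M-BMM. Adgrg6, Tmem176a, the kinase gene Fyn, Tmem176b and Sema7a were low in GM-BMM, with Fyn 7.95-fold and 4.44-fold below GM-BMDC and M-BMM. Cd5l, Slc13a3, Cd55, Raver2 and Ptprm were high in M-BMM, with Cd55 19.6-fold and 39.7-fold above GM-BMM and GM-BMDC. H2-M2, Plxdc2, Klk1b11, Mmp12 and the fibronectin gene Fn1 were low in M-BMM, with Fn1 27.1-fold and 35.7-fold below GM-BMM and GM-BMDC. Against GM-BMDC, the limma calls of Adgrg6, Tmem176a and Tmem176b ended with only the groups compared, as without either M-BMM array, and without GM-BMDC replicate 1. Those of Adgrg6 and Tmem176a also ended without GM-BMDC replicate 2 or with a trended and robust variance. In GM-BMM against M-BMM, limma called none of Adgrg6, Tmem176a, Tmem176b and Sema7a without M-BMM replicate 1 or without M-BMM replicate 2. Adgrg6 was not called there with only the groups compared (limma adjusted p = 0.0634), the same as without either GM-BMDC array. Nor was it with a trended and robust variance (0.17), quantile normalization again (0.0507) or the Y-linked covariate (0.134, log2 difference -2.32). Folds also moved with the setting, here in GM-BMDC against GM-BMM. With GM-BMDC replicate 1 or replicate 2 left out, the log2 difference was -3.05 and -4.34 for Fcgr4 and -2.80 and -4.39 for Klra2. Without GM-BMM replicate 1 or replicate 2, the log2 difference was -4.37 and -3.02 for Fcgr4, -4.28 and -2.91 for Klra2, 1.76 and 4.21 for Adgrg6, 1.37 and 2.98 for Tmem176a and 1.30 and 2.57 for Tmem176b. Sema7a had log2 differences of 3.17 and 4.34 without both GM-CSF arrays numbered 1 or both numbered 2. In GM-BMM against M-BMM, folds moved too. Leaving out GM-BMM replicate 1 or replicate 2 gave log2 differences of -1.72 and -4.16 for Adgrg6, -2.38 and -3.99 for Tmem176a and -1.96 and -3.23 for Tmem176b. In GM-BMDC against M-BMM, Fcgr4 and Klra2 moved. With GM-BMDC replicate 1 or replicate 2 left out, the log2 difference was -4.38 and -5.67 for Fcgr4 and -3.20 and -4.79 for Klra2. With the Y-linked covariate, Fcgr4 and Klra2 were at -4.21 and -3.09 there.

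**Figure D4:**
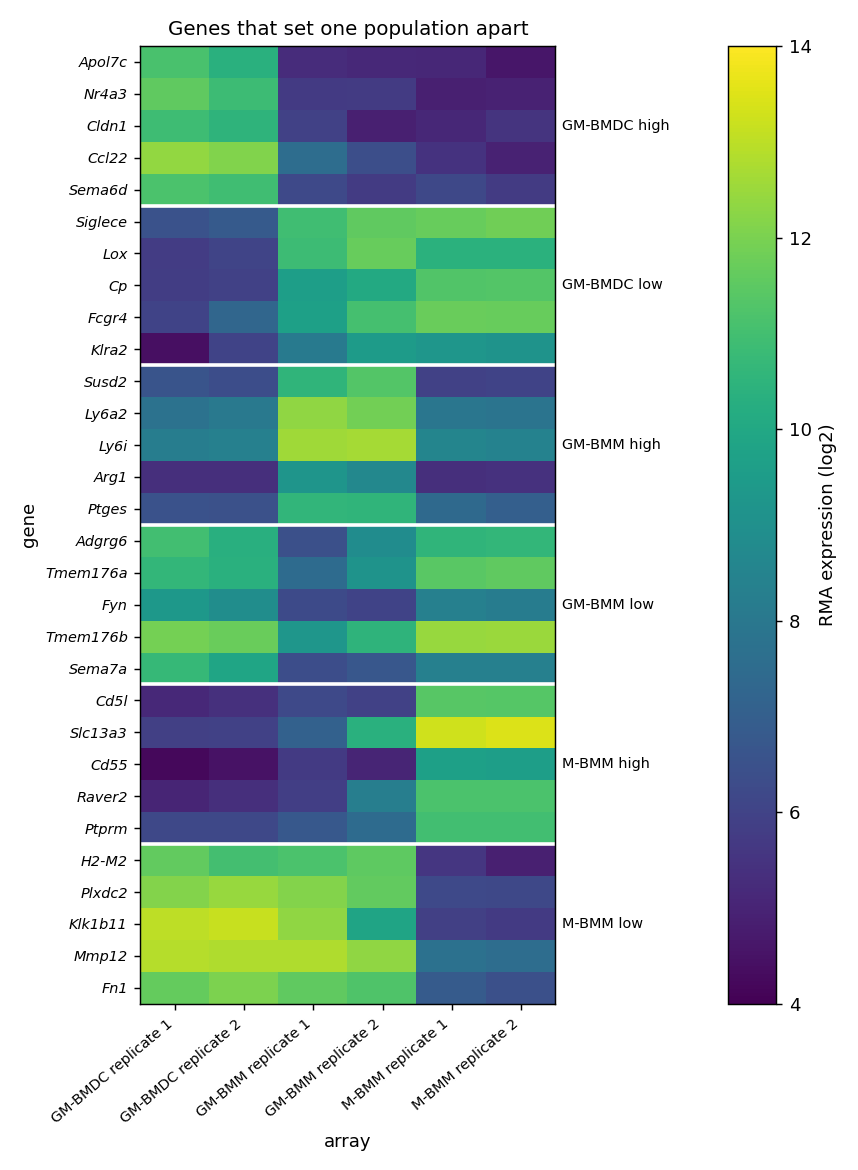
RMA log2 expression, on a colour scale from 4 to 14, of the 5 genes with the largest smaller difference in each of the 6 sets of genes that set a population apart, with a column for each array. Cd5l and Cd55 were bright in both M-BMM arrays alone.

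Lists of other cell types that a marrow culture or a gate could hold were read in the same way. The counts below are of genes higher and lower in GM-BMDC against GM-BMM, in GM-BMM against M-BMM and in GM-BMDC against M-BMM, in that order. B lymphocyte genes gave 5 and 0, 0 and 1 and 3 and 1 of 14, or 7 and 1, 0 and 1 and 6 and 2 adjusted over the list alone, and passed in the first comparison (camera adjusted p = 0.00668, or p = 0.518 with an estimated correlation), a call that ended without GM-BMDC replicate 1 (camera adjusted p = 0.0844) or both GM-CSF arrays numbered 1 (0.208). There, Cd79a of the B cell receptor complex was 5.46-fold (2.45 ± 0.30) higher, and the CD20 gene Ms4a1 3.30-fold (1.72 ± 0.24). Neutrophil and granule genes passed in the second comparison as well, with 5 of 23 higher and 1 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.000279, or p = 0.336 with an estimated correlation), which ended without GM-BMM replicate 1 (camera adjusted p = 0.0578) or both GM-CSF arrays numbered 1 (0.0648). In it the collagenase gene Mmp8 was 14.6-fold (3.87 ± 0.45) higher, and Wfdc21 3.09-fold (1.63 ± 0.17). Eosinophil genes gave 2 and 0, 2 and 0 and 3 and 0 of 10, or 2 and 0, 2 and 0 and 6 and 1 adjusted over the list alone, and passed in the third comparison (camera adjusted p = 0.00788, or p = 0.414 with an estimated correlation). In that comparison the ribonuclease gene Rnase2a was 9.21-fold (3.20 ± 0.57) higher, and Siglecf 1.60-fold (0.68 ± 0.18). The list also passed in camera in the first comparison without GM-BMM replicate 1 (adjusted p = 0.0027) and in the second without GM-BMM replicate 2 (8.34e-05). Mmp8 was no longer called by limma without M-BMM replicate 2 (adjusted p = 0.0599). Rnase2a missed the limma threshold without GM-BMDC replicate 1 (adjusted p = 0.0517), M-BMM replicate 1 (0.0866), M-BMM replicate 2 (0.0739) or with a trended and robust variance (0.0552). Siglecf did not pass in limma without GM-BMDC replicate 1 (adjusted p = 0.161), GM-BMDC replicate 2 (0.119), M-BMM replicate 1 (0.25), M-BMM replicate 2 (0.136), with the replicate block (0.0528) or with the Y-linked covariate (0.164). Cd79a (4.24) and Ms4a1 (4.78) were low in GM-BMM. Cd79a had log2 differences of 1.73 and 3.17 in GM-BMDC against GM-BMM without both GM-CSF arrays numbered 1 or both numbered 2. Rnase2a (4.59) was low in M-BMM. Rnase2a had a log2 difference of 2.43 in GM-BMDC against M-BMM with the Y-linked covariate.

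Other lists passed camera in no comparison. Plasmacytoid dendritic cell markers gave 2 and 2, 0 and 0 and 2 and 3 of 9, or 2 and 3, 1 and 2 and 3 and 4 adjusted over the list alone (camera adjusted p = 0.98, 0.439 and 0.993). Against M-BMM, the inhibitory receptor gene Lair1 was 6.59-fold (-2.72 ± 0.28) lower in GM-BMDC and the transcription factor gene Spib 3.27-fold (1.71 ± 0.25) higher. This list's mean and median were 0.07 and -0.15 in the first comparison, where the test pointed down, and -0.11 and 0.16 in the third. Mast cell and basophil genes gave 0 and 0, 1 and 0 and 3 and 0 of 15, or 0 and 0, 1 and 0 and 3 and 0 adjusted over the list alone (camera adjusted p = 0.987, 0.0906 and 0.314), with a mean of 0.26 and a median of -0.01 in the third comparison. They passed without GM-BMM replicate 2 in the second (camera adjusted p = 0.00539). Their largest differences against M-BMM were those of the serotonin transporter gene Slc6a4 at 4.35-fold (2.12 ± 0.43) and Cd200r3 at 2.46-fold (1.30 ± 0.17) higher. T and NK lymphocyte genes gave 2 and 0, 0 and 1 and 3 and 1 of 18, with the same counts adjusted over the list alone (camera adjusted p = 0.117, 0.455 and 0.0671). They passed limma's fry, which does not compare a list with other genes, in GM-BMDC against GM-BMM (adjusted p = 0.0122) and M-BMM (0.0129), and had a mean of -0.02 and a median of 0.06 in the second comparison. Klrk1, an activating receptor gene, was 12.4-fold (3.63 ± 0.15) higher in GM-BMDC than in M-BMM, Cd6 2.66-fold (1.41 ± 0.16) higher and Cd4 2.95-fold (-1.56 ± 0.18) lower. Spib lost its limma call without M-BMM replicate 1 (adjusted p = 0.05). Slc6a4 was no longer called by limma without GM-BMDC replicate 2 (adjusted p = 0.07), M-BMM replicate 1 (0.109), M-BMM replicate 2 (0.106), with a trended and robust variance (0.0536) or with the Y-linked covariate (0.0648). Cd200r3 (3.88) and Klrk1 (4.83) were low in M-BMM.

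Erythroid and megakaryocyte genes gave 1 and 1, 2 and 1 and 2 and 1 of 12, or 1 and 1, 2 and 2 and 2 and 1 adjusted over the list alone (camera adjusted p = 0.985, 0.444 and 0.592). The carbonic anhydrase gene Car2 was 22.3-fold (4.48 ± 0.57) and the platelet chemokine gene Ppbp 5.02-fold (2.33 ± 0.46) higher in GM-BMDC than in M-BMM. Fibroblast and stromal genes gave 1 and 1, 1 and 0 and 1 and 0 of 20, or 1 and 1, 2 and 0 and 1 and 0 adjusted over the list alone (camera adjusted p = 0.887, 0.464 and 0.936), with the leptin receptor gene Lepr 2.25-fold (1.17 ± 0.17) higher in GM-BMDC than in M-BMM. For this list the mean and median were -0.09 and 0.00 in the first comparison and 0.01 and -0.01 in the third. Without GM-BMDC replicate 1 or replicate 2, the log2 difference was 3.85 and 5.10 for Car2. Ppbp missed the limma threshold without GM-BMDC replicate 2 (adjusted p = 0.0667), M-BMM replicate 1 (0.0504), M-BMM replicate 2 (0.116), with a trended and robust variance (0.0546) or with the Y-linked covariate (0.06). Car2 (4.78) and Lepr (4.15) were low in M-BMM. Car2 had a log2 difference of 3.56 with the Y-linked covariate.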

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

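The settings chosen after seeing the data were those without both GM-CSF arrays numbered 1, without both numbered 2, with the crossed replicate block and with the Y-linked covariate. Over 25 alternatives, 195 of the counts and distances stayed within their bounds and 78 moved. Without single arrays, genes higher in GM-BMDC minus GM-BMM ranged from 549 to 880 and genes lower in GM-BMDC minus GM-BMM from 550 to 1175. Genes higher in GM-BMM minus M-BMM ranged from 217 to 804 and genes lower in GM-BMM minus M-BMM from 92 to 543, and genes higher in GM-BMDC minus M-BMM from 731 to 1602 and genes lower in GM-BMDC minus M-BMM from 557 to 1810. Genes GM-BMDC high ranged from 377 to 718, genes GM-BMDC low from 228 to 733, genes GM-BMM high from 90 to 315, genes GM-BMM low from 11 to 66, genes M-BMM high from 77 to 376 and genes M-BMM low from 135 to 481. The distance GM-BMDC minus GM-BMM ranged from 0.495 to 0.583, the distance GM-BMM minus M-BMM from 0.452 to 0.529 and the distance GM-BMDC minus M-BMM from 0.628 to 0.697. Leaving an array out leaves 2 residual degrees of freedom. Where it is from the population not compared, the fit is that of only the groups compared and folds stay. The causes of other moves were not tested.

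Fitting only the groups compared gave 549 genes higher in GM-BMDC minus GM-BMM and 658 genes lower in GM-BMDC minus GM-BMM, with 479 for genes GM-BMDC high, 417 for genes GM-BMDC low and 47 for genes GM-BMM low. Testing every probe set gave 733 genes lower in GM-BMDC minus GM-BMM and 335 genes lower in GM-BMM minus M-BMM. A limma treat test against 1.5-fold gave 248 genes higher in GM-BMDC minus GM-BMM and 242 genes lower in GM-BMDC minus GM-BMM, 240 genes higher in GM-BMM minus M-BMM and 74 genes lower in GM-BMM minus M-BMM, and 520 genes higher in GM-BMDC minus M-BMM and 351 genes lower in GM-BMDC minus M-BMM. Requiring 2-fold gave 437 and 498, 426 and 177, and 771 and 614 in the same order, by construction fewer. Without moderation, limma gave 0 and 0, 6 and 2, and 8 and 9, against 3686, 3075 and 4628 genes at an unadjusted p under 0.05. Keeping genes above the 50th percentile of the values gave distances of 0.670, 0.599 and 0.840, and above the 25th percentile 0.713 for the distance GM-BMDC minus M-BMM, both by dropping weakly expressed genes.

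Leaving out both GM-CSF arrays numbered 1 gave 127 for genes GM-BMM low. Leaving out both numbered 2 gave 1168 genes higher in GM-BMM minus M-BMM and 880 genes lower in GM-BMM minus M-BMM, 471 for genes GM-BMM high, 128 for genes GM-BMM low, 617 for genes M-BMM high and 632 for genes M-BMM low, with 0.529 for the distance GM-BMM minus M-BMM and 0.697 for the distance GM-BMDC minus M-BMM. The Y-linked covariate gave 302 genes lower in GM-BMM minus M-BMM, 1029 genes lower in GM-BMDC minus M-BMM and 209 for genes M-BMM high. With the replicate block the totals were 1963, 1176 and 3060 genes, against 2079, 1235 and 3323 without it and 2002, 1121 and 3155 with the M-BMM numbers crossed. Replicate deviations correlated across genes at 0.024, 0.026 and -0.132 between pairs of populations. Replicate 1 minus replicate 2 was -4.86 in GM-BMDC and -5.44 in GM-BMM for Y-linked Eif2s3y, but 0.98 and 6.65 for Xist. The numbers split both alike in Y-linked RNA, not in Xist, and a pairing is not settled. The mean of the list type I interferon response in GM-BMM minus M-BMM was 0.573 without GM-BMM replicate 1 and reversed to -0.124 without GM-BMM replicate 2 and to -0.124 with both numbered 2 left out, and the cause was not tested.

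Of 52 list calls, 52 were kept with the replicate block, 50 with the Y-linked covariate, 48 above the 50th percentile, 44 on ranks, 31 with fry and 0 with an estimated correlation, and between 47 and 51 without single arrays. Lists that camera had not called passed in 4 cases with fry, T and NK lymphocyte genes and chemokine receptors in GM-BMDC against both others, in 9 without GM-BMM replicate 2, in 12 without both numbered 2 and in 6 or fewer in other settings. Of 278 calls of named genes, 206 were kept without M-BMM replicate 1 and 206 without M-BMM replicate 2, between 251 and 268 without any other single array, 252 with a trended and robust variance, 254 with only the groups compared, 262 with the Y-linked covariate and 271 or more in the other settings that included them.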

Other observations

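All 9 tests in this part were chosen after the values they concern had been seen.

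Sex-linked RNA set the GM-CSF arrays apart from a label that reads male for each array. In the arrays numbered 1, the Y-linked gene nearest to the M-BMM mean was Kdm5d at -3.08 log2, with Eif2s3y and Uty farther below, and Xist was high, at 11.66 in GM-BMDC and 11.58 in GM-BMM, so cells of female mice are a candidate explanation there. In GM-BMDC replicate 2 the smallest excess of Xist and the 3 Y-linked genes over the arrays that lack them was 2.3 log2, and on a linear scale Xist reached 51.7% and the Y-linked genes 59.6% of the arrays that have them, which is consistent with RNA of both sexes in that array. An exchange among arrays of male mice alone is argued against by the 3 arrays with Xist more than 3 log2 above the lowest. Mice of both sexes, pooled RNA and an exchange with samples outside the series stay open as untested, and a difference of sex, donor or culture between replicates was not separated from other spread between them.

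GM-BMDC replicate 2 had more RNA of several macrophage genes than GM-BMDC replicate 1, with Adgre1 at 10.90 against 9.39, Itgam at 10.75 against 9.67 and Maf at 7.69 against 6.38, but also of the dendritic cell gene Cd209a, at 11.69 against 9.04. Over 64 genes high in both macrophage populations, the median share of macrophage RNA that would raise replicate 2 to its level was 8.4%. Cells carried over from the GM-BMM gate would bring genes high in GM-BMM alone, but over 29 of these the median share was 0.052 of that value (95% bootstrap interval -0.078 to 0.188), and for cells with the M-BMM profile the ratio over 19 genes was 0.001 (-0.109 to 0.055). For the genes and arrays read here, both argue against carry-over of either population as the cause. A macrophage-like cell of another profile, and a difference of donor, sex or culture, stay open as untested.

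The 2 GM-BMM arrays differed by more than 1 log2 in 240 genes, of which 134 were higher in replicate 1, such as Ccl17 (10.74 against 6.74) and Mgl2 (9.47 against 5.87), and 106 in replicate 2, such as Slc13a3 (10.35 against 7.10) and the fractalkine receptor gene Cx3cr1 (9.76 against 6.94). GM-BMDC cells in replicate 1 are argued against as the whole cause: both GM-BMDC arrays lay at or below replicate 1 in 82 of the 134 genes. Cells with the M-BMM profile in replicate 2 are argued against likewise, with both M-BMM arrays at or below it in 58 of 106. Median shares were 3.6% (95% bootstrap interval 1.7 to 6.7) over 99 genes high in GM-BMDC and 10.8% (3.5 to 22.7) over 31 for M-BMM. The upper bounds raise only 2 and 10 genes to their level, largely due to the 1 log2 cut. A smaller carry-over as part of the difference cannot be told apart from a difference within the population. A difference of donor, sex or culture may contribute and was not tested apart from these.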
